A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

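Poly-A RNA of budding yeast, Saccharomyces cerevisiae strain W303a, was sequenced in 8 libraries. Per the labels' protocols, cells were grown at 30 °C in YPD with 2% dextrose to an OD600 of 0.2 to 0.4 and then held at 30 °C or 39 °C for 5 min. Libraries labelled with 5ph-IAA came from cells in which the protein Ifh1 was to be depleted. The treatment protocol describes 1 µM β-estradiol together with 5 µM 5ph-IAA, an auxin analogue that triggers degradation of a degron-tagged protein, for 30 min. The series' design text speaks instead of anchor away, a method that moves a nuclear protein out of the nucleus, so the sources used here describe the depletion in different ways. They do not say whether cells without 5ph-IAA received a solvent, β-estradiol or nothing, nor whether both kinds of cells carried the same tagged strain. Ifh1 is a coactivator of ribosomal protein genes that acts together with the DNA-bound factors Fhl1 and Rap1.

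The authors deposited 1 table per library with estimated counts and TPM (transcripts per 1000000 transcripts) for 6034 coding targets, made with kallisto per the submitters' processing notes. The version of kallisto, the transcript set and the genome build are not given in the sources used here. Kallisto shares a read that fits several targets among them, which left 6.89% to 7.51% of the deposited estimated counts not whole, and values of near-identical copies (duplicated ribosomal protein genes, EFT1 and EFT2, HXT6 and HXT7, Ty elements) therefore depend on that sharing. The library kit (TruSeq RNA v2, per the labels' protocols) does not mark strand, so reads from genes that overlap on opposite strands cannot be told apart. Target lengths were multiples of 3 for 99.97% of targets and the effective length was 199 bases shorter in the median, so a target is a coding sequence and very short ones are poorly measured: 137 targets were shorter than 200 bases. Of the 137 ribosomal protein genes in the list used here, 6 (RPL29, RPL39, RPL41A, RPL41B, RPS29A and RPS29B, none longer than 180 bases) were listed at 0 in every library and were not tested. The tables gave no symbol for 939 targets, which kept their systematic names.

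Libraries were placed in 4 groups of 2 from their titles, temperature and replicate labels. The labels number the replicates as biological ones but do not speak of separate cultures, so the p-values measure the spread between these samples. The estimated counts summed to 8917417 and 9068802 in the 30 °C control libraries, 21025464 and 19974567 at 39 °C, 7717767 and 10007034 at 30 °C with 5ph-IAA, and 10118860 and 9298953 at 39 °C with 5ph-IAA. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.28 to 4.32 over genes with at least 10 counts, so the 2 libraries of a group were not copies of each other. Pearson's r of log2 TPM between replicates was 0.990 to 0.996 across genes.

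The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr on the groups) in R 4.3.3. One fit held all 8 libraries with a term per group, which left 4 residual degrees of freedom, and 5734 of 6034 targets passed the filter. All tests were 2-sided, p-values were adjusted by Benjamini-Hochberg over the tested genes of a comparison, and 0.05 was the threshold. A fold change given with ± carries its standard error, and a TPM given with ± carries the SD of 2 libraries. The comparisons were heat shock without 5ph-IAA, 5ph-IAA at 30 °C, heat shock with 5ph-IAA, 5ph-IAA at 39 °C, and the interaction, which is the heat shock change with 5ph-IAA minus the change without it. On simulated counts with 200 changed genes, the same fit recovered 88.3% of genes changed 1.5-fold and 95.8% of those changed 2-fold in heat shock without 5ph-IAA (5653 genes), 81.9% and 95.2% for 5ph-IAA at 30 °C (5656 genes), and 77.6% and 85.5% for the interaction (5652 genes). Of the calls made there, 15 of 205, 8 of 188 and 18 of 194 were false. All simulated libraries were drawn around the 30 °C control level, with the 200 genes changed in a single group. They held no wide response or shift in composition, whereas 44.5% to 82.2% of tested genes were called in the real comparisons. The simulated rates therefore need not hold for the real comparisons.

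Genes were grouped in 21 lists: ribosomal proteins, Hsf1 chaperones, Msn2/4 stress genes, ribosome biogenesis, RNA polymerase I and III, translation factors, glycolysis, proteasome, mitochondrial ribosome, oxidative phosphorylation, endoplasmic reticulum folding, galactose genes, drug export genes, amino acid synthesis, histones, iron and zinc uptake, a-cell genes, alpha-cell genes, meiosis and sporulation, ribosomal protein regulators and stress regulators. KAR2 stands in both the Hsf1 chaperone and the endoplasmic reticulum folding list. Each list was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. On simulated data camera placed 3 of 100 random lists under the threshold. Genes were drawn independently there, so this does not test the preset correlation for lists whose members vary together. The estimated correlation was 0.539 for ribosomal proteins and 0.546 for glycolysis. It was below the preset 0.01 for iron and zinc uptake (−0.042) and for the proteasome (0.001). Even so, the iron and zinc call for 5ph-IAA at 39 °C was lost (camera, adjusted p = 0.00819 against 0.149). The proteasome call in heat shock without 5ph-IAA was lost too (0.00496 against 0.0881). A call lost in this setting is therefore no evidence by itself that the members vary together. With the estimated correlation, the calls that held were those of the Msn2/4, ribosome biogenesis and RNA polymerase I and III lists in both heat shock comparisons and in the interaction, of the Msn2/4 list for 5ph-IAA at 30 °C, and of the ribosome biogenesis, RNA polymerase I and III and proteasome lists for 5ph-IAA at 39 °C. Members past the edgeR threshold were counted with p adjusted over all genes and adjusted over the list alone.

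The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the regulators of ribosomal protein genes and of stress, the 6 largest rises and 6 largest falls among called genes with at least 10 TPM and no overlap between the groups, and of each list the 4 members with the smallest adjusted p and the 2 with the largest change, or any member of a list of at most 10 genes. A gene named in 1 comparison may be given in the others. Genes outside the rule are said to be so where they appear.

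The labels name no spike-in, so all changes are relative to the other transcripts of a library. TMM set the median log2 fold change of all tested genes close to 0 in every comparison (−0.02 to 0.04). Scaling by library totals alone moved that median to −0.03 in heat shock without 5ph-IAA, 0.38 for 5ph-IAA at 30 °C, −0.32 in heat shock with 5ph-IAA, 0.14 for 5ph-IAA at 39 °C and −0.26 in the interaction, and the deposited TPM moved it to 0.17, 0.61, −0.21, 0.28 and −0.35. Directions below are therefore relative to the median gene. The alternatives were DESeq2 1.42.0, median-of-ratios size factors, library totals, TMM without the responsive lists, no filter on low counts, summed counts of paralogs, limma on log2(TPM + 1), only the groups compared, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Thinning every library to 7717767 counts was added after the data were seen. Positions were taken from the R64 reference annotation, not from the authors: 6031 of 6034 target identifiers matched it and 6018 had the same coding length. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.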

Results

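The transcriptome of budding yeast was measured by poly-A RNA sequencing after a 5 min shift from 30 °C to 39 °C, with and without prior treatment with 5ph-IAA to deplete Ifh1, the coactivator of ribosomal protein genes. Each of the 4 combinations of temperature and treatment had 2 libraries, and their totals ranged from 7717767 to 21025464 estimated counts, with the deepest libraries in the 39 °C group without 5ph-IAA. The ribosomal protein genes together held 40.2% ± 0.685 of TPM (SD, n = 2) at 30 °C without 5ph-IAA, 19.6% ± 0.370 at 39 °C without it, 17.2% ± 0.0967 at 30 °C with it and 10.3% ± 0.0258 at 39 °C with it. In each of these comparisons the 2 libraries of one group lay on one side of the 2 libraries of the other, and an exact permutation test of 2 against 2 libraries (two-sided) gave p = 0.333, the smallest it can give. The Hsf1 chaperone list, targets of the heat shock factor Hsf1, went from 0.759% ± 0.0155 of TPM at 30 °C to 9.42% ± 0.0916 at 39 °C (SD, n = 2). In cells with 5ph-IAA this list held 1.01% ± 0.0037 and 9.01% ± 0.0702.

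**Figure D1:**
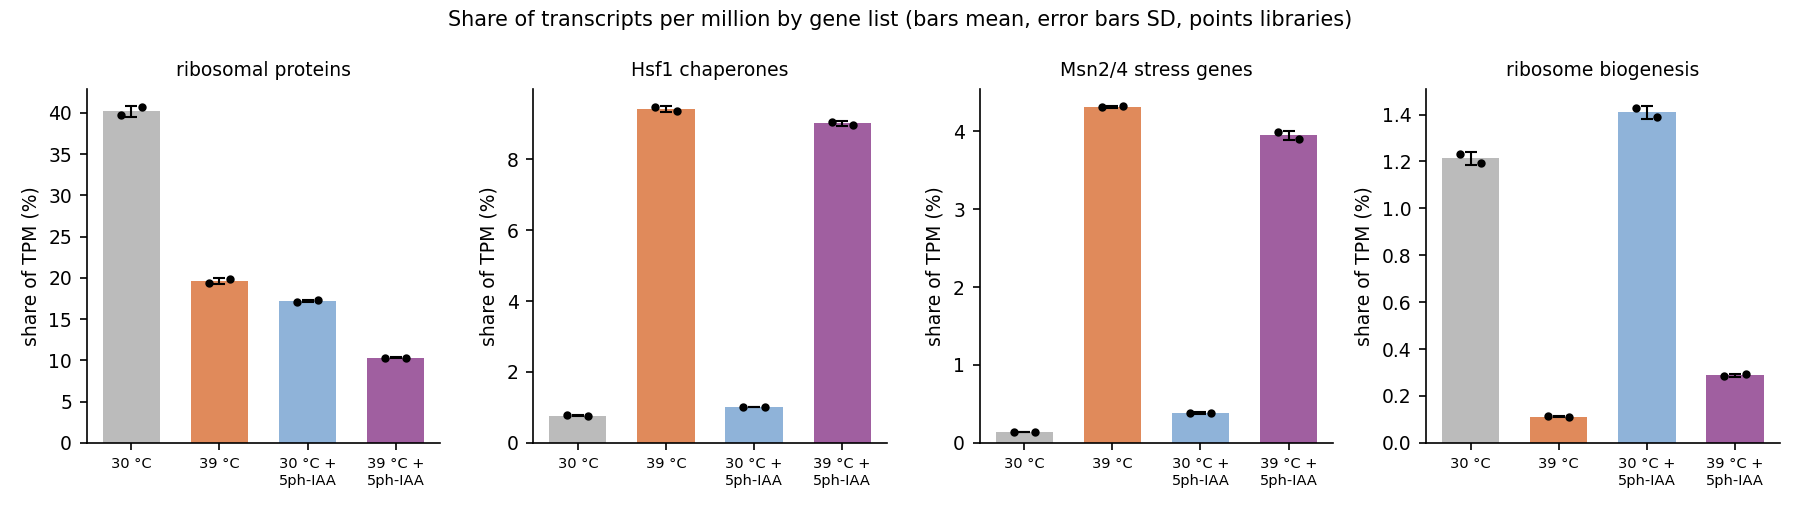
Share of TPM (%, vertical axis) held by 4 gene lists in the 4 groups of libraries. Bars show the mean of 2 libraries, error bars the SD and points the libraries: the ribosomal protein share was highest at 30 °C without 5ph-IAA (40.2%) and lowest at 39 °C with it (10.3%), while the Hsf1 chaperone share was 9.42% and 9.01% at 39 °C.

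IFH1 (YLR223C), which encodes the depleted protein, lies on chromosome XII at 582233 to 585490 of R64 in a single coding exon. Its level was 24.05 and 22.56 TPM in the 30 °C libraries, 10.1 and 9.06 at 39 °C, 26.64 and 23.99 at 30 °C with 5ph-IAA, and 13.74 and 14.3 at 39 °C with 5ph-IAA. IFH1 mRNA fell by 1.41 ± 0.07 on the log2 scale on heat shock without 5ph-IAA (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.11e-10) and by 0.62 ± 0.07 with it (adjusted p = 2.02e-06). For 5ph-IAA at 30 °C its log2 fold change was −0.53 ± 0.06 (adjusted p = 1.41e-05), but −0.13 (adjusted p = 0.1) with library totals alone and 0.11 on the log2(TPM + 1) scale. The depletion described in the labels acts on the protein, so the mRNA level does not check the treatment labels. FHL1 (YPR104C, chromosome XVI, 733623 to 736433), the DNA-bound partner of Ifh1, fell by 0.61 ± 0.10 on heat shock without 5ph-IAA (adjusted p = 5.61e-05).

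Heat shock without 5ph-IAA asked how cells with Ifh1 respond to 39 °C. Within 5 min, chaperone and stress genes had risen and genes for making ribosomes had fallen. SSA4 (YER103W, chromosome V, 364589 to 366517), a heat-inducible Hsp70 chaperone, went from 15.6 ± 0.529 to 7197 ± 203 TPM (SD, n = 2), a log2 fold change of 8.72 ± 0.06 (edgeR, adjusted p = 2.68e-18). HSP42 (YDR171W, chromosome IV, 806621 to 807748), a small heat shock protein that gathers misfolded proteins, went from 48.7 ± 3.02 to 7648 ± 91.3 TPM (log2 fold change 7.17 ± 0.05, adjusted p = 1.98e-18). NSR1, a nucleolin-like factor of rRNA processing, went from 1008 ± 12.9 to 10.7 ± 0.15 TPM (log2 fold change −6.68 ± 0.06, adjusted p = 1.53e-17). In all 3 genes both 39 °C libraries lay on the same side of both 30 °C libraries.

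All 25 Hsf1 chaperones rose in this comparison, as did 25 of 25 when adjusted over the list alone, with a median log2 fold change of 4.04 (camera, adjusted p = 6.81e-12; adjusted p = 0.0732 with an estimated correlation). They included the mitochondrial disaggregase HSP78 (6.84 ± 0.05), the Hsp90 chaperone HSP82 (6.08 ± 0.04) and the sorting factor BTN2 (7.79 ± 0.07). All 30 Msn2/4 stress genes, targets of the general stress factors Msn2 and Msn4, rose as well, also when adjusted over the list alone (median 4.76, camera, adjusted p = 5.7e-13). Among them were the small heat shock protein HSP26 (8.76 ± 0.08), the trehalose synthase subunit TSL1 (7.22 ± 0.07), the cytosolic catalase CTT1 (6.69 ± 0.06) and the hexokinase HXK1 (6.04 ± 0.05). DDR2, a further member, had 0 counts in both 30 °C libraries and 35 and 32 at 39 °C, so it was at least 5.16-fold higher at a floor of 3 counts per library, and with it set at this bound the list median was 4.65. Outside the lists, TMA10, a ribosome-associated protein (9.30 ± 0.08), and RGI1, a respiratory growth gene (8.40 ± 0.08), were among the 6 largest rises.

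Of the 131 ribosomal protein genes tested, 130 fell and none rose, the same counts as adjusted over the list alone, with a median log2 fold change of −1.22 (camera, adjusted p = 9.03e-21; adjusted p = 0.286 with an estimated correlation). The exception was RPL15B, which lies outside the naming rule and was chosen after its values were seen. The largest falls were those of RPL22B (−3.75 ± 0.09), RPS27A (−3.35 ± 0.08) and RPS9A (−3.06 ± 0.05), while RPL3 (YOR063W, chromosome XV, 444686 to 445849) went from 3505 ± 170 to 877.1 ± 0.283 TPM (−2.13 ± 0.04). Ribosome biogenesis genes fell further, 74 of 74 also adjusted over the list alone, with a median of −3.77 (camera, adjusted p = 1.89e-23). NOG1 and NOG2, GTPases of large subunit assembly, had log2 fold changes of −5.37 ± 0.06 and −6.24 ± 0.08, and UTP13 of the small subunit processome had −5.57 ± 0.07. All 19 subunits of RNA polymerase I and III fell, also adjusted over the list alone (median −2.52, camera, adjusted p = 4.13e-08), with RPA43 at −4.52 ± 0.07 and RPA135 at −3.83 ± 0.06. Of 26 translation factors 24 fell and 1 rose, also adjusted over the list alone (median −1.54, camera, adjusted p = 9.56e-08; adjusted p = 0.0968 with an estimated correlation). YEF3, the fungal elongation factor, fell by 2.52 ± 0.04 and NIP1, an initiation factor subunit, fell by 3.02 ± 0.06. Among the 6 largest falls were PHO84, a phosphate transporter (−5.98 ± 0.08), PUF6, an RNA-binding assembly factor of the ribosome (−5.65 ± 0.06), and REI1, a cytoplasmic maturation factor of the large subunit (−5.80 ± 0.08).

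Other lists moved as well. Genes of endoplasmic reticulum folding rose in 11 of 14 cases and fell in 2 (median 0.77, camera, adjusted p = 0.0112; adjusted p = 0.286 with an estimated correlation), led by the Hsp70 KAR2 (3.39 ± 0.04) and the oxidase ERO1 (3.21 ± 0.04). Of 10 drug export genes 7 rose (median 1.01, camera, adjusted p = 0.0124; adjusted p = 0.292 with an estimated correlation), among them the transporters PDR15 (3.81 ± 0.06) and SNQ2 (2.73 ± 0.04). Proteasome genes rose in 24 of 32 cases, 23 adjusted over the list alone, by a median of 0.28 (camera, adjusted p = 0.00496; adjusted p = 0.0881 with an estimated correlation), and their activator RPN4 rose by 3.66 ± 0.05. Of 31 genes of oxidative phosphorylation 20 rose and 4 fell (median 0.61, camera, adjusted p = 0.00976; adjusted p = 0.361 with an estimated correlation), with the hypoxic cytochrome c CYC7 at 6.18 ± 0.08. Mitochondrial ribosome genes fell in 52 of 66 cases and rose in 6 (median −0.46, camera, adjusted p = 1.7e-05; adjusted p = 0.0881 with an estimated correlation). Amino acid synthesis genes fell in 18 of 22 cases and rose in 2 (median −0.73, camera, adjusted p = 0.00028; adjusted p = 0.286 with an estimated correlation), with the methionine synthase MET6 at −2.48 ± 0.05. Apart from the proteasome, the counts of these lists were the same adjusted over the list alone. Of 5 a-cell genes, which mark the mating type of this strain, 4 fell and 1 rose, but the list did not pass camera (median −2.55, adjusted p = 0.0722), and the pheromone receptor STE2 fell by 2.55 ± 0.05.

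Among the regulators, TOD6, a repressor of ribosome biogenesis genes, fell by 4.60 ± 0.07, and SFP1, an activator of ribosomal genes, rose by 0.96 ± 0.05. Of the 7 stress regulators 6 rose, HSF1 (YGL073W, chromosome VII, 368753 to 371254) by 1.04 ± 0.05, MSN2 by 1.16 ± 0.06 and MSN4 by 0.86 ± 0.06, and GCN4, the activator of amino acid synthesis, fell by 1.29 ± 0.05 (edgeR, each with an adjusted p under the threshold). The stress regulator list had a median of 0.86 and passed camera narrowly (adjusted p = 0.0491; adjusted p = 0.285 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.0507), without either library of the 30 °C 5ph-IAA group (0.0539 and 0.054) and without either library of the 39 °C 5ph-IAA group (0.0574 and 0.0586). In all, 2438 genes were higher and 2274 lower at 39 °C among 5734 tested (edgeR quasi-likelihood, Benjamini-Hochberg), or 82.2% of genes, and 1092 and 986 of them changed at least 2-fold.

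The comparison of 5ph-IAA with control at 30 °C asked what Ifh1 depletion does to cells that were not heated. Ribosomal protein genes fell almost without exception, stress genes of the Msn2/4 list rose, and the Hsf1 chaperones did not move as a group. Of 131 ribosomal protein genes 130 fell and none rose, also adjusted over the list alone, with a median log2 fold change of −2.01 (camera, adjusted p = 1.83e-52; adjusted p = 0.167 with an estimated correlation). RPL8A went from 775.9 ± 2.01 to 177.5 ± 3.29 TPM (SD, n = 2), a log2 fold change of −2.78 ± 0.06 (edgeR, adjusted p = 4.3e-13). Other large falls included those of RPL22B (−2.86 ± 0.09), RPL31B (−2.60 ± 0.05) and RPS13 (−2.31 ± 0.04). RPS4A (−2.08 ± 0.04), named for its small adjusted p, lay near the list median.

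The falls were unequal. RPS28A (−0.86 ± 0.07), RPL4A (−0.87 ± 0.04), RPL1A (−0.96 ± 0.06) and RPL18B (−0.99 ± 0.06) fell least among the genes called, and RPL15B, the 1 gene not called, had −0.10 ± 0.11. The log2 fold change of RPL15B was 0.10 without control replicate 1 and −0.28 without control replicate 2 (edgeR, adjusted p = 0.48 and 0.0462), and 0.30 with library totals alone. RPL15B, RPS28A, RPL1A and RPL18B lie outside the naming rule and were chosen after their values were seen. RPL3 fell by 1.33 ± 0.04. Counts summed over paralogs gave a fall in all 74 ribosomal protein features.

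Of the 30 Msn2/4 stress genes 26 rose and none fell, 27 adjusted over the list alone, with a median of 0.90 (camera, adjusted p = 8.56e-14), or 0.89 without DDR2. The median was 1.30 with library totals alone and 1.5 from TPM. TSL1 went from 5.58 ± 0.645 to 49.7 ± 4.09 TPM (2.50 ± 0.07), HXK1 from 46.3 ± 0.587 to 357.1 ± 19.4 TPM (2.30 ± 0.05), GPH1, glycogen phosphorylase, rose by 2.25 ± 0.06 and PGM2, phosphoglucomutase, by 1.92 ± 0.07. Of the 25 Hsf1 chaperones 7 rose and 11 fell, 12 adjusted over the list alone, and the list was not called (median −0.09, mean 0.00, camera, adjusted p = 0.846). Its median was 0.31 with library totals alone and 0.56 on the log2(TPM + 1) scale. CUR1, a BTN2 paralogue (0.97 ± 0.08), HSP78 (0.81 ± 0.04) and the disaggregase HSP104 (YLL026W, chromosome XII, 88623 to 91349; 0.60 ± 0.05) rose, while the Hsp70 SSA2 (−0.65 ± 0.03) and its exchange factor SSE1 (−0.59 ± 0.04) fell, with values of 0.00 and 0.06 on the log2(TPM + 1) scale.

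The remaining lists moved by less than the ribosomal protein genes, and the direction of most depended on the scaling. Ribosome biogenesis genes fell in 66 of 74 cases, 68 adjusted over the list alone (median −0.42, camera, adjusted p = 3.62e-12; adjusted p = 0.0584 with an estimated correlation), but their median was −0.02 with library totals and 0.23 from TPM. NSR1 fell by 0.92 ± 0.05 and NOG2 by 1.00 ± 0.05. RNA polymerase I and III genes fell in 15 of 19 cases (median −0.30, camera, adjusted p = 0.00101; adjusted p = 0.167 with an estimated correlation), with a median of 0.10 under library totals and 0.35 from TPM. Translation factors fell in 25 of 26 cases (median −0.33, camera, adjusted p = 2.7e-07, or 0.167 with an estimated correlation), with 0.07 under library totals and 0.32 from TPM. The elongation factor EFT2 fell by 1.09 ± 0.04, which is uncertain because kallisto splits the reads it shares with its paralog EFT1. All 16 glycolysis genes fell (median −0.53, camera, adjusted p = 1.64e-07; adjusted p = 0.31 with an estimated correlation), with −0.13 under library totals and 0.12 from TPM, and TDH1, a glyceraldehyde phosphate dehydrogenase, fell by 1.35 ± 0.10. Histone genes fell in 6 of 8 cases (median −0.38, camera, adjusted p = 0.00763; adjusted p = 0.361 with an estimated correlation), with 0.01 under library totals and 0.26 from TPM. Amino acid synthesis genes fell in 20 of 22 cases (median −0.66, camera, adjusted p = 1.05e-08; adjusted p = 0.168 with an estimated correlation), a median that was −0.26 under library totals and −0.01 from TPM, led by HIS4 (−1.74 ± 0.05) and ARG1 (−1.60 ± 0.07). Proteasome genes fell in 15 of 32 cases and rose in 1, RPN9 (median −0.13, camera, adjusted p = 0.0281; adjusted p = 0.167 with an estimated correlation). That median was 0.27 under library totals and 0.52 from TPM. The call was lost without control replicate 2 (adjusted p = 0.0605) and without replicate 1 of the 30 °C 5ph-IAA group (adjusted p = 0.0627). The counts of these last 6 lists were the same adjusted over the list alone. GCN4 fell by 0.70 ± 0.05, or had −0.05 on the log2(TPM + 1) scale (limma, adjusted p = 0.247).

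Among single genes, TIR1, a cell wall mannoprotein, rose from 10.3 ± 2.35 to 112.3 ± 10.2 TPM (2.79 ± 0.14), and GSY1, glycogen synthase, rose by 2.66 ± 0.10. HXT7, a hexose transporter, rose by 2.74 ± 0.05, which is uncertain because its coding sequence is nearly identical to that of HXT6. BSC1 went from 94.2 ± 0.628 to 3.36 ± 0.991 TPM (−5.41 ± 0.14) and its neighbour PRM7 from 92.7 ± 2.2 to 5.24 ± 0.0422 TPM (−4.79 ± 0.09). HAC1, the regulator of the unfolded protein response, fell by 1.28 ± 0.07, while RPN4 (0.77 ± 0.06), MSN4 (0.64 ± 0.06) and MSN2 (0.60 ± 0.06) rose. With edgeR and Benjamini-Hochberg adjustment 1351 genes were higher and 1614 lower with 5ph-IAA, 51.7% of those tested, and 142 and 242 changed at least 2-fold. The split was 3962 higher and 503 lower with library totals alone, and 4865 and 276 with limma on log2(TPM + 1).

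**Figure D2:**
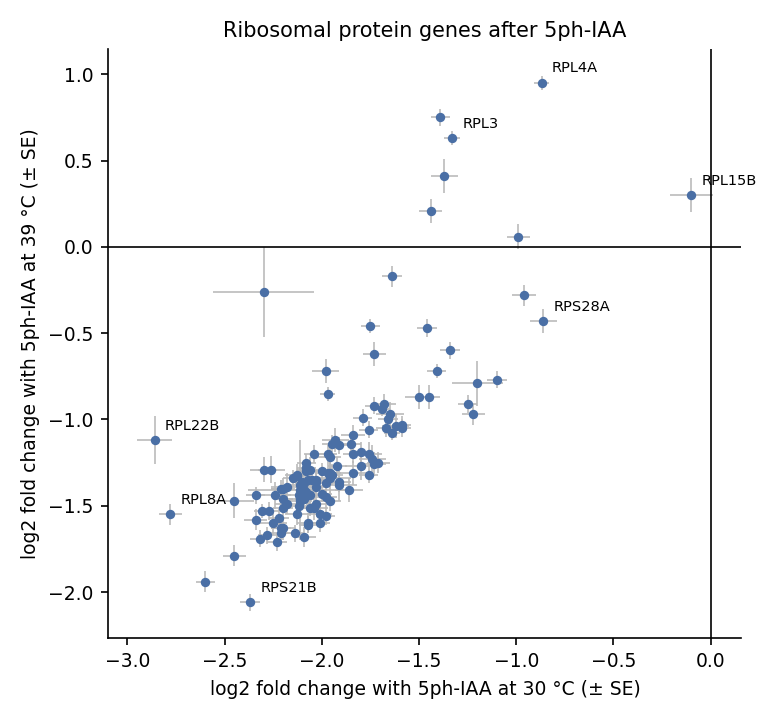
Log2 fold change of 131 ribosomal protein genes with 5ph-IAA at 30 °C (horizontal axis) and at 39 °C (vertical axis), 1 point per gene with bars of 1 standard error. Most genes lie below 0 on both axes, RPL4A (−0.87 and 0.95) and RPL3 (−1.33 and 0.63) lie above 0 at 39 °C only, and Pearson's r across the genes is 0.762.

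Heat shock with 5ph-IAA asked whether the response to 39 °C runs without Ifh1. Chaperone and stress genes rose, and ribosomal protein genes, already low, fell by a smaller factor. SSA4 went from 31.8 ± 2.84 to 6388 ± 120 TPM (SD, n = 2), a log2 fold change of 7.88 ± 0.06 (edgeR, adjusted p = 6.6e-18), and HSP42 from 81.2 ± 0.351 to 7666 ± 14.6 TPM (6.79 ± 0.05). All 25 Hsf1 chaperones rose, also adjusted over the list alone, with a median of 3.63 (camera, adjusted p = 3e-14; adjusted p = 0.0518 with an estimated correlation), among them BTN2 (7.86 ± 0.07), HSP78 (5.69 ± 0.04) and HSP82 (5.34 ± 0.04). All 30 Msn2/4 stress genes rose, also adjusted over the list alone (median 3.67, camera, adjusted p = 1.4e-14), with HSP26 at 6.90 ± 0.07, CTT1 at 5.94 ± 0.06 and TSL1 at 5.02 ± 0.05. TMA10 (6.66 ± 0.07) and HSP30, a plasma membrane stress protein (7.25 ± 0.08), were among the 6 largest rises.

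Of 131 ribosomal protein genes 124 fell and 1 rose, also adjusted over the list alone, by a median of −0.55 (camera, adjusted p = 3.48e-14; adjusted p = 0.39 with an estimated correlation). The gene that rose was RPL15B, chosen after its values were seen. RPL22B fell by 2.01 ± 0.14, RPS9A by 1.58 ± 0.06, RPS0B by 0.93 ± 0.05 and RPL3 by 0.17 ± 0.04. All 74 ribosome biogenesis genes fell, also adjusted over the list alone (median −2.23, camera, adjusted p = 1.78e-23), with NSR1 at −5.50 ± 0.07, NOG2 at −4.87 ± 0.09 and NOG1 at −3.61 ± 0.05. All 19 RNA polymerase I and III genes fell, also adjusted over the list alone (median −1.43, camera, adjusted p = 8.27e-08), with RPA43 at −2.57 ± 0.07. Translation factors fell in 23 of 26 cases and rose in 2, also adjusted over the list alone (median −0.78, camera, adjusted p = 5.25e-06; adjusted p = 0.176 with an estimated correlation), with NIP1 at −2.35 ± 0.06 and YEF3 at −1.16 ± 0.04. REI1 (−5.45 ± 0.09), the ribosome assembly factor ALB1 (−4.76 ± 0.13) and PHO84 (−4.68 ± 0.07) were among the 6 largest falls. Mitochondrial ribosome genes fell in 50 of 66 cases and rose in 1 (median −0.35, camera, adjusted p = 5.1e-06; adjusted p = 0.083 with an estimated correlation). Amino acid synthesis genes fell in 17 of 22 cases and rose in 3 (median −0.33, camera, adjusted p = 0.00728; adjusted p = 0.39 with an estimated correlation). Genes of oxidative phosphorylation rose in 21 of 31 cases and fell in 2 (median 0.41, camera, adjusted p = 0.00289; adjusted p = 0.39 with an estimated correlation). With library totals alone the medians of these 3 lists were −0.68, −0.65 and 0.08, and from TPM −0.59, −0.54 and 0.18. The ribosomal protein median was −0.88 with library totals alone and −0.78 from TPM. The exceptions MRP8, ARG4, HIS5 and LYS1 (amino acids), and ATP5 and ATP20 (respiration) were chosen after their values were seen. MRP8 stands in the mitochondrial ribosome list by its name pattern alone, and whether it belongs there was not checked. The counts of these 3 lists were the same adjusted over the list alone. TOD6 fell by 2.84 ± 0.07, and RPN4 (2.86 ± 0.05), HSF1 (0.80 ± 0.05), KAR2 (3.04 ± 0.04) and ERO1 (3.12 ± 0.04) rose.

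In this comparison 2178 genes were higher and 2194 lower (edgeR, Benjamini-Hochberg), 76.2% of those tested, with 825 and 565 changed at least 2-fold. The split was 1409 higher and 3156 lower with library totals alone and 1577 and 2835 with limma on log2(TPM + 1). Of the genes higher in heat shock, 1975 were shared by cells without and with 5ph-IAA, where independent lists would share 926, and of the genes lower 1912 were shared, where independent lists would share 870. These comparisons share no library. Across 5734 genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.875 and a Spearman's rho of 0.898, and the slope of the response with 5ph-IAA on that without was 0.659. Over 5300 genes with a mean of at least 10 CPM r was 0.924.

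**Figure D3:**
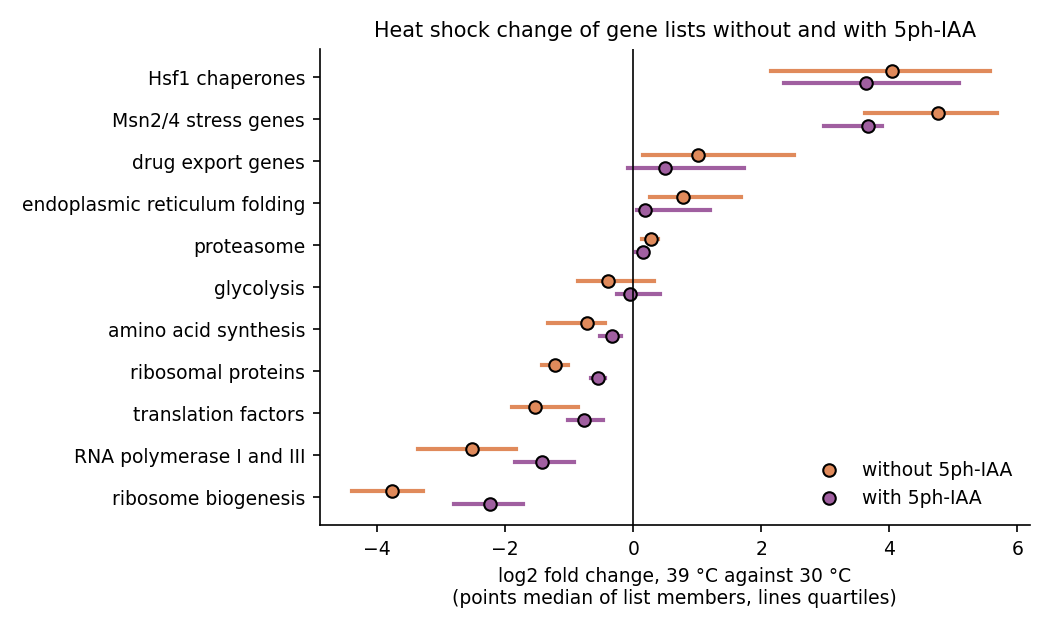
Median log2 fold change of 11 gene lists on heat shock (horizontal axis) without and with 5ph-IAA, with lines from the lower to the upper quartile of the list members. The ribosome biogenesis median moved from −3.77 to −2.23 and the Hsf1 chaperone median from 4.04 to 3.63.

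At 39 °C, the comparison of cells with and without 5ph-IAA asked how Ifh1 depletion alters heat-shocked cells. Ribosomal protein genes were again lower, whereas genes for making ribosomes were higher. RPS21B went from 2887 ± 41.6 TPM without to 849.5 ± 14.7 with 5ph-IAA (SD, n = 2), a log2 fold change of −2.06 ± 0.05 (edgeR, adjusted p = 6.71e-11). RPF2, an assembly factor of the large subunit, went from 5.81 ± 0.294 to 25.8 ± 1.05 TPM (1.85 ± 0.08, adjusted p = 9.09e-10). Of 131 ribosomal protein genes 122 fell and 6 rose, 123 and 6 adjusted over the list alone, with a median of −1.32 (camera, adjusted p = 2.74e-45; adjusted p = 0.177 with an estimated correlation). RPL31B (−1.94 ± 0.06), RPL31A (−1.71 ± 0.05) and RPS13 (−1.53 ± 0.04) fell, and RPL4A (0.95 ± 0.04) and RPL3 (0.63 ± 0.04) rose. Ribosome biogenesis genes rose in 69 of 74 cases and fell in 1, 70 and 1 adjusted over the list alone (median 1.20, camera, adjusted p = 6.1e-31). UTP13 (1.69 ± 0.09), NOC2 (1.66 ± 0.06) and the methyltransferase NOP1 (1.30 ± 0.04) stood among the members that rose, and RCL1, chosen after its values were seen, fell. ARX1, an export factor of the large subunit (1.77 ± 0.09), and the helicase RRP3 (1.65 ± 0.08), which are not in the list, rose too. RNA polymerase I and III genes rose in 17 of 19 cases, also adjusted over the list alone (median 0.75, camera, adjusted p = 1.46e-09), with RPA43 at 1.66 ± 0.09 and RPA190 at 1.38 ± 0.05.

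Translation factors rose in 18 of 26 cases and fell in 4, also adjusted over the list alone (median 0.38, camera, adjusted p = 0.000154; adjusted p = 0.18 with an estimated correlation), and YEF3 rose by 0.76 ± 0.04. The translation factor median was 0.67 from TPM. Of 25 Hsf1 chaperones 23 fell and none rose, 24 adjusted over the list alone (median −0.34, camera, adjusted p = 3.87e-09; adjusted p = 0.117 with an estimated correlation), a median that was −0.05 from TPM. The cyclophilin CPR6 fell by 0.58 ± 0.04, KAR2 by 0.45 ± 0.04 and SSA4 by 0.46 ± 0.04. Of 30 Msn2/4 stress genes 6 rose and 11 fell, also adjusted over the list alone, and the list was not called (median −0.06, camera, adjusted p = 0.353), with a median of 0.08 under library totals and 0.23 from TPM. HSP12, a membrane-protecting stress protein, fell by 0.85 ± 0.06, and GSY2, glycogen synthase, rose by 0.53 ± 0.04. Proteasome genes fell in 27 of 32 cases, also adjusted over the list alone, by a median of −0.25 (camera, adjusted p = 5.18e-08) that was −0.10 under library totals and 0.04 from TPM. Genes of endoplasmic reticulum folding fell in 11 of 14 cases and rose in 1, also adjusted over the list alone (median −0.37, camera, adjusted p = 0.00106; adjusted p = 0.179 with an estimated correlation), with SIL1, an exchange factor of KAR2, at −0.94 ± 0.06 and a list median of −0.08 from TPM. All 5 a-cell genes rose, also adjusted over the list alone (median 0.77, camera, adjusted p = 0.000592; adjusted p = 0.149 with an estimated correlation), among them the a-factor transporter STE6 (1.15 ± 0.05) and STE2 (0.81 ± 0.05).

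Of the other lists called at 39 °C, none kept its call with an estimated correlation. Amino acid synthesis genes fell in 12 of 22 cases and rose in 2, 13 and 3 adjusted over the list alone (median −0.25, camera, adjusted p = 0.00188; adjusted p = 0.37 with an estimated correlation), with a median of 0.04 from TPM. Glycolysis genes fell in 11 of 16 cases and rose in 2 (median −0.21, camera, adjusted p = 0.00345; adjusted p = 0.458 with an estimated correlation), with 0.09 from TPM. Drug export genes fell in 7 of 10 cases and rose in 1, PDR15 (median −0.28, camera, adjusted p = 0.0144; adjusted p = 0.37 with an estimated correlation), with 0.01 from TPM. Genes of oxidative phosphorylation fell in 13 of 31 cases and rose in 4 (median −0.10, camera, adjusted p = 0.0336; adjusted p = 0.473 with an estimated correlation), with 0.04 under library totals. This call was lost without replicate 2 of either 39 °C group (adjusted p = 0.104 without and 0.107 with 5ph-IAA). Histone genes fell in 4 of 8 cases (median −0.13, camera, adjusted p = 0.0497; adjusted p = 0.458 with an estimated correlation), with 0.01 under library totals. The histone call was lost when any 1 of the 30 °C libraries was left out (adjusted p = 0.0501 to 0.054) and without replicate 2 of either 39 °C group (0.12 and 0.115). The members that rose (ILV1 and LYS9 for amino acids, PFK1 and PDC1 for glycolysis, QCR2, COX5B, ATP1 and ATP2 for respiration) were chosen after their values were seen. Except for amino acid synthesis, the counts of these 5 lists were the same adjusted over the list alone.

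The hexose transporters HXT6 (1.80 ± 0.12, uncertain because of HXT7) and HXT5 (−1.87 ± 0.07) changed in opposite directions, DIA1, a gene linked to filamentous growth, fell by 1.89 ± 0.06, and TOD6 rose by 1.13 ± 0.09. IFH1 mRNA rose by 0.26 ± 0.07 (edgeR, adjusted p = 0.00927), a call lost without replicate 2 of the 39 °C libraries (0.20, adjusted p = 0.0974). With edgeR 1292 genes were higher and 1260 lower, 44.5% of those tested, and 139 and 147 changed at least 2-fold. The split was 2315 higher and 709 lower with library totals alone, and 3224 and 371 with limma on log2(TPM + 1). Genes called at 30 °C and at 39 °C overlapped by 526 lower, where independent lists would share 355, and by 307 higher, where independent lists would share 304. Across all 5734 genes, which are not independent replicates, the 5ph-IAA changes at both temperatures had a Pearson's r of 0.302 and a Spearman's rho of 0.058, and across the 131 ribosomal protein genes 0.762 and 0.793.

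The interaction asked which genes responded to heat by a different amount after 5ph-IAA, where a positive value means a smaller fall or a larger rise. Genes for ribosomes and for their assembly fell less on heat shock after 5ph-IAA, and Msn2/4 stress genes rose less. Ribosomal protein genes started lower with 5ph-IAA at 30 °C (median −2.01) and were still lower at 39 °C (median −1.32). Ribosome biogenesis genes were instead higher with 5ph-IAA at 39 °C (median 1.2). Msn2/4 stress genes started higher with 5ph-IAA at 30 °C (median 0.90) and were not called as a list at 39 °C (median −0.06, camera, adjusted p = 0.353). Their smaller rise thus reflects the higher start more than a lower level at 39 °C. NOC2 went from 159.3 ± 2.79 to 9.76 ± 0.567 TPM without and from 188.7 ± 3.23 to 37.8 ± 2.75 TPM with 5ph-IAA (SD, n = 2), an interaction of 2.06 ± 0.08 on the log2 scale (edgeR, adjusted p = 5.37e-10). Ribosome biogenesis genes had a positive interaction in 72 of 74 cases and a negative one in 1, or 72 and 2 adjusted over the list alone (median 1.60, camera, adjusted p = 3.96e-28), including ERB1 (2.12 ± 0.09), UTP4 (2.10 ± 0.08) and NOP1 (1.68 ± 0.06). Ribosomal protein genes had a positive interaction in 129 of 131 cases and a negative one in none, 130 adjusted over the list alone (median 0.66, camera, adjusted p = 1.26e-25; adjusted p = 0.262 with an estimated correlation). That median was 0.41 with library totals alone and 0.31 from TPM. They were large for RPL4B (2.14 ± 0.06), RPL3 (1.95 ± 0.05) and RPL4A (1.83 ± 0.06), and RPS2 had 1.12 ± 0.05. RNA polymerase I and III genes (17 of 19 positive, also adjusted over the list alone, median 1.06, camera, adjusted p = 3.18e-09) included RPA135 (1.97 ± 0.08) and RPA190 (1.89 ± 0.07). Translation factors were positive in 23 of 26 cases, 24 adjusted over the list alone (median 0.72, camera, adjusted p = 2.77e-09; adjusted p = 0.119 with an estimated correlation), and YEF3 had 1.37 ± 0.05. From TPM the RNA polymerase I and III median was 0.68 and the translation factor median 0.35.

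Msn2/4 stress genes had a negative interaction in 26 of 30 cases and a positive one in none, 27 adjusted over the list alone (median −1.08, camera, adjusted p = 1.68e-13), with HXK1 at −2.36 ± 0.06, TSL1 at −2.20 ± 0.08 and GPH1 at −2.01 ± 0.07. In TPM, the level of HXK1 and TSL1 at 39 °C was higher with 5ph-IAA (3918 ± 29 and 1374 ± 6.12) than without (3333 ± 16.8 and 911.3 ± 21.9), and so was the level at 30 °C. The TPM scale also moved the median gene, by 0.28 at 39 °C and 0.61 at 30 °C. On the TMM scale the HXK1 interaction was about as large as its rise at 30 °C, so HXK1 was not clearly higher at 39 °C. The TSL1 interaction was somewhat smaller in size than its rise at 30 °C. Hsf1 chaperones were negative in 16 of 25 cases and positive in 4, also adjusted over the list alone (median −0.31, camera, adjusted p = 0.000763; adjusted p = 0.262 with an estimated correlation), with CUR1 at −1.27 ± 0.09, HSP78 at −1.15 ± 0.06 and HSP104 at −0.93 ± 0.06. Drug export genes were negative in 7 of 10 cases (median −0.52, camera, adjusted p = 0.00521; adjusted p = 0.262 with an estimated correlation), with SNQ2 at −0.94 ± 0.06 and PDR5 (YOR153W, chromosome XV, 619840 to 624375) at −0.92 ± 0.07. Amino acid synthesis genes were positive in 18 of 22 cases and negative in 1 (median 0.39, camera, adjusted p = 4.58e-05; adjusted p = 0.262 with an estimated correlation), and MET6 had 0.98 ± 0.07. The counts of both lists were the same adjusted over the list alone. From TPM the medians were −0.66 for Hsf1 chaperones, −0.73 for drug export genes and 0.03 for amino acid synthesis.

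Among the 6 largest interactions in each direction were BSC1 (5.02 ± 0.27), PRM7 (3.92 ± 0.13), the polyamine transporter TPO2 (3.43 ± 0.10), MGA1, a factor related to heat shock factors (3.01 ± 0.17), RGI1 (−3.10 ± 0.11) and the decarboxylase ARO10 (−2.88 ± 0.07). ARO10 rose from 50.5 ± 0.211 to 662.4 ± 14.1 TPM without 5ph-IAA, against levels of 187.4 ± 4.41 and 261.3 ± 8.51 TPM with it. Among regulators, TOD6 (1.76 ± 0.11) and IFH1 (0.79 ± 0.10) had positive interactions, and MSN2 (−0.84 ± 0.08) and RPN4 (−0.79 ± 0.07) negative ones. With edgeR 1490 genes had a positive and 1315 a negative interaction, 48.9% of those tested, and 329 and 184 of them were at least 2-fold. The split was 908 positive and 2550 negative with library totals alone, and 685 and 2948 with limma on log2(TPM + 1).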

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

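The 3 tests of explanations in this part were all chosen after the result was seen, whereas the interaction test itself was fixed earlier. The results below came up because the response to heat differed between cells without and with 5ph-IAA by the interaction test (edgeR quasi-likelihood with Benjamini-Hochberg adjustment for genes, camera for lists), with 1490 genes positive and 1315 negative. Among lists that make ribosomes, the median log2 interaction was 1.60 for ribosome biogenesis, 1.06 for RNA polymerase I and III, 0.72 for translation factors (adjusted p = 0.119 with an estimated correlation) and 0.66 for ribosomal proteins (adjusted p = 0.262 with an estimated correlation). The ribosomal protein genes started lower with 5ph-IAA at 30 °C (median −2.01) and were still lower at 39 °C (median −1.32). Single genes of these lists were ERB1 (2.12), UTP4 (2.10), NOC2 (2.06), NOP1 (1.68), RPA135 (1.97), RPA190 (1.89), YEF3 (1.37), RPL4B (2.14), RPL3 (1.95), RPL4A (1.83) and RPS2 (1.12).

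Ribosome biogenesis genes fell less on heat shock after 5ph-IAA. Of 6 scalings compared, DESeq2 repeated the median-of-ratios scaling, and only library totals and TPM moved the median gene far from the main fit. Scaling as the cause is argued against, since over these scalings, which moved other lists across 0, the median interaction of the list was 1.19 to 1.64 and its lower quartile never below 0.77. The deeper sequencing of the heat shock libraries without 5ph-IAA does not account for it either, because thinning all libraries to the same total left a median of 1.59. A weaker heat stress in the treated cultures cannot be told apart, as the ratio of the medians with over without 5ph-IAA was 0.899 for Hsf1 chaperones, 0.77 for Msn2/4 stress genes and 0.592 for ribosome biogenesis, and no library measures the stress apart from the genes, and the Msn2/4 ratio reflects a higher level at 30 °C (median 0.90 with 5ph-IAA) more than a lower one at 39 °C (median −0.06, not called), so it says little on this. That Ifh1 depletion itself may blunt the fall is a hypothesis the design names, and it was not tested separately from the compounds.

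Stress lists had medians of −1.08 (Msn2/4 stress genes, adjusted p = 0.0121 with an estimated correlation) and −0.31 (Hsf1 chaperones, where the call was lost, adjusted p = 0.262 with an estimated correlation), with HXK1 (−2.36), TSL1 (−2.20), GPH1 (−2.01), CUR1 (−1.27), HSP78 (−1.15) and HSP104 (−0.93). Other lists had medians of −0.52 (drug export genes), −0.28 (endoplasmic reticulum folding), −0.13 (proteasome), 0.39 (amino acid synthesis), 0.34 (glycolysis) and 0.25 (iron and zinc uptake). With an estimated correlation the adjusted p of these 6 lists was 0.262, 0.262, 0.133, 0.262, 0.352 and 0.195. From TPM the glycolysis median was −0.02, the iron and zinc uptake median −0.09, amino acid synthesis 0.03, endoplasmic reticulum folding −0.64, proteasome −0.49 and Hsf1 chaperones −0.66. The a-cell genes had a median of 1.08 (adjusted p = 0.0364; adjusted p = 0.262 with an estimated correlation), or 1.05 without control replicate 2, where the call was lost (adjusted p = 0.0554). Of 5 a-cell genes 3 had a positive interaction, and 4 had a positive and 1 a negative one adjusted over the list alone. Genes of these lists were SNQ2 (−0.94), PDR5 (−0.92), MET6 (0.98), STE6 (1.32) and STE2 (1.17). Among regulators the interaction was 1.76 for TOD6, 0.79 for IFH1, −0.84 for MSN2 and −0.79 for RPN4. The remaining genes were BSC1 (5.02), PRM7 (3.92), TPO2 (3.43), MGA1 (3.01), RGI1 (−3.10) and ARO10 (−2.88).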

How the results depend on the processing

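Thinning to the lowest total was chosen after the data were seen, and the other alternatives before. DESeq2, median-of-ratios size factors, TMM without the responsive lists, no filter on low counts, the replicate number as a block and thinning left each of 185 named gene results with the same direction and side of the threshold. With 1 library left out, where the lone library of its group is assumed to vary like the others, 1477 such gene results kept both, the exceptions being RPL15B for 5ph-IAA at 30 °C without either control library and IFH1 for 5ph-IAA at 39 °C without replicate 2 of the 39 °C libraries.

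Scaling moved the counts. Higher and lower genes numbered 3962 and 503 for 5ph-IAA at 30 °C with library totals and 4865 and 276 with limma on log2(TPM + 1). For 5ph-IAA at 39 °C they were 2315 and 709, then 3224 and 371, and in the interaction 908 and 2550, then 685 and 2948. In heat shock with 5ph-IAA library totals gave 1409 higher. Library totals change the scaling alone, while limma on log2(TPM + 1) also changes the test, the length scaling and the pseudocount, and which of these moved its counts was not tested. Library totals reversed the list medians for 5ph-IAA at 30 °C of Hsf1 chaperones (0.31), RNA polymerase I and III (0.10), translation factors (0.07), histones (0.01) and proteasome (0.27), those at 39 °C of histones (0.01) and oxidative phosphorylation (0.04), that of Msn2/4 stress genes at 39 °C (0.08) and that of iron and zinc uptake in the interaction (0.00). For 5ph-IAA at 30 °C limma on log2(TPM + 1) reversed IFH1 (0.11), SSA2 (0.00), SSE1 (0.06) and RPL15B (0.55), and library totals RPL15B (0.30). With 1 library left out RPL15B ranged from −0.28 to 0.10 and the oxidative phosphorylation median at 30 °C from −0.07 to 0.05.

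Of 21 lists, camera with an estimated correlation called 3 in heat shock without 5ph-IAA, 1 for 5ph-IAA at 30 °C, 3 in heat shock with 5ph-IAA, 3 for 5ph-IAA at 39 °C and 3 in the interaction, and fry called 21, 15, 16, 17 and 20. The ribosomal protein medians −1.22, −2.01, −0.55, −1.32 and 0.66 and the Hsf1 chaperone medians 4.04, 3.63, −0.34 and −0.31 lost their camera call with the estimated correlation, which does not alter the medians. The correlation of the heat shock responses was 0.927 and their slope 0.705 on the log2(TPM + 1) scale, and with 1 library left out they ranged from 0.822 to 0.868 and from 0.608 to 0.671. The cause was not tested.

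Replicate numbers share little, with correlations of −0.078 to 0.229 over 6 pairs of groups. As a block they gave 2435 and 2271 genes in heat shock without 5ph-IAA, 1356 and 1627 for 5ph-IAA at 30 °C, 2182 and 2197 in heat shock with it, 1292 and 1261 for 5ph-IAA at 39 °C, and 1499 and 1310 in the interaction. The histone call for 5ph-IAA at 39 °C was lost with the block (adjusted p = 0.0596). The stress regulator call in heat shock without 5ph-IAA was lost with the block (adjusted p = 0.051) and with thinning (adjusted p = 0.0514). Thinning, which removes the depth difference, gave 2353 and 2231 genes there.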

Other observations

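The 6 tests of explanations in this part were all chosen after the result was seen. At 30 °C, cells with 5ph-IAA also showed changes outside ribosomes and stress (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, log2 fold change ± standard error, 2 libraries per group). Of 10 galactose genes 3 rose and none fell (median 0.12, camera, adjusted p = 0.136), with MTH1, a repressor of hexose transporter genes, at 1.82 ± 0.12 and the reductase GCY1 at 0.95 ± 0.07. In TPM, which moved the median gene by 0.61, the mean of every galactose gene was higher with 5ph-IAA. Of 10 drug export genes 5 rose and 2 fell (median 0.18, camera, adjusted p = 0.192), with a median of 0.58 under library totals, and the transporters PDR15 (0.78 ± 0.07), SNQ2 (0.77 ± 0.04) and PDR5 (0.64 ± 0.05) were among those that rose. Of 31 genes of oxidative phosphorylation 7 rose and 8 fell, also adjusted over the list alone, and the list was not called (median 0.00, camera, adjusted p = 0.846). Among its members CYC7 (1.73 ± 0.12) and COX5B (1.26 ± 0.08) rose and CYC1 fell by 1.04 ± 0.06. DIA1 fell by 3.26 ± 0.06. ASC1, a ribosome-bound signalling protein outside the ribosomal protein list (−2.68 ± 0.06), and STM1, a ribosome-preserving factor (−1.45 ± 0.04), were chosen after their values were seen. Of 3 alpha-cell genes 1 rose, SAG1, and none adjusted over the list alone (median 0.34, camera, adjusted p = 0.354). At 39 °C, 8 of 13 iron and zinc uptake genes rose with 5ph-IAA and 1 fell, FRE1 (median 0.43, camera, adjusted p = 0.00819; adjusted p = 0.149 with an estimated correlation).

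In heat shock without 5ph-IAA 5 of 10 regulators of ribosomal protein genes rose and 4 fell (camera, adjusted p = 0.922), and the median of 0.21 and the mean of −0.38 differed in sign. Of 10 meiosis and sporulation genes 4 rose and 2 fell (median 0.40, camera, adjusted p = 0.493). Ribosomal protein genes with an intron (88 genes) and without (43 genes) had medians of −2.05 and −1.85 for 5ph-IAA at 30 °C and of −1.22 and −1.27 in heat shock. Heat shock without 5ph-IAA and 5ph-IAA at 30 °C shared 1074 higher and 1230 lower genes, where independent lists would share 574 and 640. Both comparisons use the same control libraries. Their log2 fold changes had a Pearson's r of 0.488 and a covariance of 0.565, against 0.563 and 0.0272 in simulated data with no real change, so r alone carries no information here. The simulated data held 0.4 calls shared in the same direction on average. Shared control libraries alone therefore do not give the covariance seen over all tested genes. The overlap is not answered by this simulation, because with no gene changed few calls could arise there at all. How much the shared libraries add to the overlap among changed genes was not tested. Across ribosomal protein genes r was 0.128 and the covariance 0.025, against 0.561 and 0.00265 simulated.

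Msn2/4 stress genes were higher at 30 °C after 5ph-IAA. Over 6 scalings, which moved other lists across 0, the list median was never below 0.89 and its lower quartile never below 0.53. Of these scalings, only library totals and TPM moved the median gene far from the main fit, to 0.38 and 0.61. Both moves raise the list, and no scaling tried would lower it by much. The scalings therefore cannot decide whether scaling is the cause. A partial heat shock in proportion to the 39 °C response is argued against by the Hsf1 chaperones, 25 of 25 of which lay below the value it needs, with an upper quartile of the shortfall at −0.57, a median needed of 0.76 and a median observed of −0.09 (library totals alone: 25 of 25, −0.43, 1.10 and 0.31, and TPM: 25 of 25, −0.33, 1.31 and 0.56). A response to the compounds themselves cannot be told apart, since no library holds treated cells without the degron and the drug export median depends on the scaling (0.18, with members going both ways, but 0.58 with library totals alone and 0.80 from TPM). Ifh1 depletion, which the design names, may therefore be 1 of several causes, and it was not tested alone.

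Ribosomal protein genes fell by unequal amounts after 5ph-IAA. Noise between libraries is argued against by a Pearson's r of 0.762 between the changes at 30 °C and 39 °C, which share no library. Reads shared between paralogs are argued against as the only source of the spread. With paralogs summed, the SD of the changes (0.272) was 5.4 times their median standard error (0.05) over 74 features. Over 17 single-copy genes the SD was 0.264. These values do not say how much such reads add to the spread over the genes before summing. Coding length is argued against by a Spearman's rho of −0.018 with the change at 30 °C. A candidate explanation is that promoters depend on Ifh1 to different degrees, which stays an untested hypothesis, since no measure of Ifh1 binding was analysed here.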
